A study of Rattus norvegicus with 4 samples.

How the data were processed

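Total RNA of PC12 cells was hybridised to 4 one-colour (Cy3) Agilent rat arrays, 2 with RNA of cells transfected with an empty vector and 2 with RNA of cells transfected with a MAX expression plasmid, after drug selection per the labels. Each group is 1 transfected line sampled at passages 8 and 13, per the series' design text. The p-values of single genes thus measure the spread between passages of a line. No p-value given here measures the spread between independent transfections. The deposited scanner files hold spot intensity: per the file headers, they were written by Feature Extraction 10.7.3.1 (the submitters' processing notes give 10.7) with annotation of genome build rn4. The processed intensity used here was background-subtracted and detrended within each array, per the file headers, and not scaled between arrays. The authors also deposited a value table of log2 values. Set against the scanner files, differences between its columns matched log2 processed intensity minus each array's 75th percentile (Pearson r = 1, SD of the disagreement 4.3e-07 at most), so its scale and direction are known. Each probe in it is centred on a baseline that is neither the mean nor the median of these 4 arrays and stays unknown; column medians were -0.033, -0.011, -0.005 and -0.006.

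Each array held 43379 spots other than controls, for 41012 probes. Spots with an outlier flag (89 to 140 spots on an array) were left out, as were 89 probes with no spot left on some array. Log2 processed signals of a probe's spots were averaged, and each array's 75th percentile was subtracted; that percentile was 734.6 and 640.8 signal units in the empty vector arrays and 623.2 and 710 in the MAX vector arrays. Probes well above background on an array numbered 29328 and 28217 in the empty vector group and 26411 and 28493 in the MAX vector group. Tests used the 28564 probes well above background on at least 2 of the 4 arrays, with 1 probe per gene, that with the highest mean, which gave 25356 genes. The median log2 fold change of all these genes was -0.019, and no scaling tried moved it by over 0.1. Gene symbols came only from RefSeq accessions in the files, matched without versions to the RefSeq gene table of assembly GRCr8: 10768 of 41012 probes (26.3%) were named, with 8899 distinct names, and the others kept the files' identifiers. Of the genes tested, 6285 had a symbol, so a gene list covers only part of its members: 483 of 738 were measured. No coordinates are given, since the builds differ.

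Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3.94 total degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05; ± is the SE of a log2 fold change unless stated. Where a probe was well above background on no array of a group, the fold is a lower bound: the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal well above background on that array. Where it was well above background on 1 of a group's 2 arrays, the fitted value is given with that number and rests in part on a signal near background. Of the 213 calls, 32 higher and 16 lower ones were well above background on neither array of the dimmer group. A total of 27 gene lists was fixed before the data were examined, of which 26 had at least 5 measured members. They were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists, and 5 passed. With the preset, its p-values rest on the spread among genes and not between arrays. Estimated correlations of these 5 lists ran from 0.024 to 0.477. With an estimated correlation 0 lists passed, nor did any at an unadjusted p under 0.05 (count 0). That version also rests on 2 residual degrees of freedom, so few lists could pass it whatever their correlation. Neuronal differentiation, estimated at 0.024, went from an unadjusted camera p of 2.17e-06 to 0.0517. By fry, 1 list passed for a shift in one direction and 19 for change in either direction. Named genes followed a rule fixed at the same time: the 12 largest rises and 12 largest falls among genes that passed, had a symbol and were well above background on every array, 4 genes with bounds, up to 3 members of each list per direction, and 28 genes of the MAX, HIF and chromaffin systems. Some genes the rule names are not reported here. Members of lists named beyond these were chosen after their values were seen.

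The steps were tested on simulated data with the means of these 25356 genes and 200 changed genes in each of 5 runs. Each gene's spread was drawn at random from the distribution that limma fitted to all genes, whatever its signal level. Of genes changed 2-fold, 3.58% were recovered, of those changed 4-fold 72.5% and of those changed 16-fold 93%; 5.55% of calls were false. So a 2-fold change of a gene would mostly be missed in data of this kind. A spread that depends on signal level was not simulated, so recovery of bright genes may differ. Data drawn from limma's own model hold the false share near the threshold, so that share does not check the real calls. A list of 30 genes shifted by 0.5 on the log2 scale had an unadjusted camera p under 0.05 in 5 of 5 runs. Genes were simulated independently of each other, so this does not cover lists of correlated genes. Alternatives covered normexp background correction, quantile and median scaling, 3 other filters on dim probes, every probe or the mean of a gene's probes, an intensity trend, robust moderation, the authors' value table, the replicate number and the slide as blocks, an adjusted p under 0.10, each array left out, and, for lists, an estimated correlation and fry. Normexp used median spot signals, because the files read here give no mean signal, and an offset of 50 signal units. Such an offset lowers the folds of dim probes, so the size of a fold there, the lower bounds included, depends on the background correction. The scan day was planned as a block, but all 4 arrays were scanned on 1 day. Slide 1 held both empty vector arrays and MAX vector replicate 2, and slide 2 held MAX vector replicate 1, so the fit with the slide as a block equals the fit within slide 1. The figures were drawn with matplotlib in Python.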

Results

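Gene expression was measured in PC12 cells, a rat line derived from a pheochromocytoma, the catecholamine-producing tumour of adrenal chromaffin cells. PC12 cells are known to lack a functional MAX, the partner protein through which MYC proteins bind DNA. Of the 2 groups, one line carried an empty vector and the other a plasmid that codes for MAX. Each line was sampled at passages 8 and 13, which gave 2 one-colour arrays per group. Between 64.4% and 71.53% of 41012 probes were well above background on an array, and 0 spots were saturated. Across probes, the Pearson correlation of log2 signal was 0.9953 between the empty vector arrays, 0.9914 between the MAX vector arrays and 0.9849 to 0.989 between the groups. Replicates differed by a median of 0.12 on the log2 scale in the empty vector group and 0.15 in the MAX vector group. With 4 arrays, the number of arrays limits the precision.

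The comparison addresses what a MAX plasmid changes in these cells, with chromaffin features, HIF genes and proliferation as the themes the series names. The Max probe was not well above background on any of the 4 arrays. Its log2 signals relative to each array's 75th percentile were -8.36 and -8.07 in the empty vector group and -7.61 and -7.94 in the MAX vector group. Where this probe lies relative to the plasmid's sequence was not analysed here, so it does not check the labels. Mnt and Pnmt had no probe named here.

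In cells with the MAX vector, Mmp3, Ppp1r1a, Spp1, Npy and Th rose, while Nefm, Vcam1 and Ddc fell. Mmp3, which encodes stromelysin-1, was 139-fold higher (log2 fold change 7.12 ± 0.12, SE, n = 2 arrays per group). Ppp1r1a, which encodes a protein phosphatase inhibitor, was 69-fold higher (6.11 ± 0.13). Both had an adjusted p of 0.00648 in limma. With normexp, a background correction that here adds 50 signal units to every signal and so draws the folds of dim probes toward 1, they had 4.98 and 4.91 on the log2 scale. Th, the rate-limiting enzyme of catecholamine synthesis, was 4.42-fold higher (2.15 ± 0.11, adjusted p = 0.0203). Ddc, which encodes the next enzyme of that pathway, fell by 1.08 ± 0.08 on the log2 scale (adjusted p = 0.0391). Nefm, the middle neurofilament subunit, fell by 2.40 ± 0.11 (adjusted p = 0.0197). In all, 213 of 25356 genes passed an adjusted p of 0.05 in limma, 146 higher and 67 lower, and 211 of them changed at least 2-fold. Of the 213, 91 carried a gene symbol, 66 higher and 25 lower. With the replicate number as a block, 0 genes passed in limma (3885 at an unadjusted p under 0.05). With the slide as a block, which rests on the 3 arrays of slide 1, only Mmp3 and Ppp1r1a of the genes with a symbol kept their call. Spp1, Npy, Th, Nefm, Vcam1 and Ddc lost theirs. Their log2 fold changes there were 3.7, 3.06, 2.1, -2.37, -1.96 and -1.09. With empty vector replicate 1 or 2 left out, 0 genes passed in limma (1963 and 2456 at an unadjusted p under 0.05), with MAX vector replicate 2 left out 144 passed, and with no filter on dim probes 0 passed (4033 at an unadjusted p under 0.05, against 4091 with the filter).

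**Figure D1:**
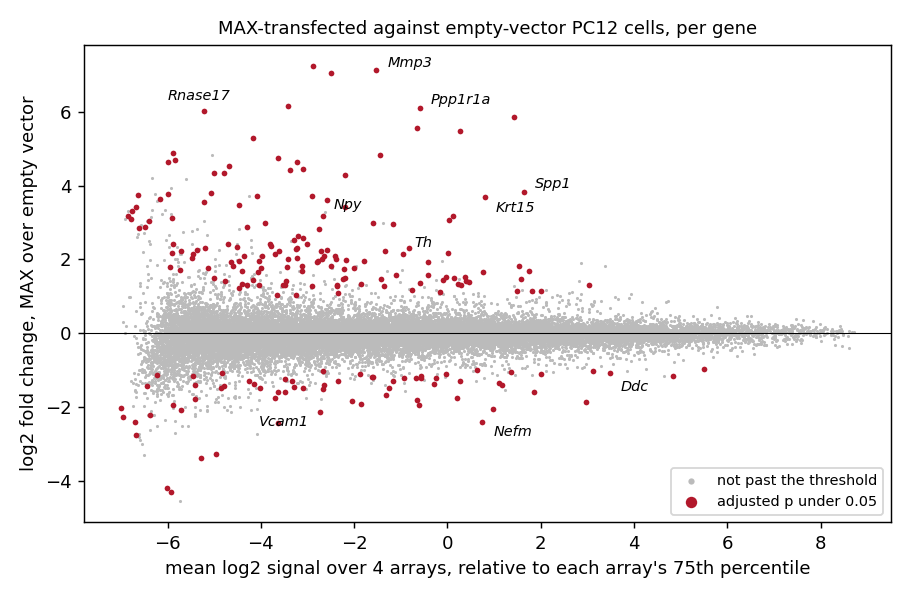
Log2 fold change of MAX vector over empty vector cells for each of 25356 genes, against the mean log2 signal over 4 arrays relative to each array's 75th percentile. Red points are the 213 genes with an adjusted p under 0.05 in limma; Mmp3 lies at 7.12 and Nefm at -2.40, and Rnase17, not well above background in the empty vector group, is drawn at its fitted value although only a bound is known.

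Among the 12 genes with a symbol that rose most, passed and were well above background on every array, Spp1, which encodes the secreted matrix protein osteopontin, was 14.2-fold higher (3.83 ± 0.12, adjusted p = 0.0159). Npy, which encodes neuropeptide Y, was 9.05-fold higher (3.18 ± 0.14, adjusted p = 0.0197). The epithelial keratin genes Krt15, Krt13 and Krt19 were 12.9-, 12.2- and 9.11-fold higher (3.68 ± 0.28, 3.61 ± 0.30 and 3.19 ± 0.18). Adgrf5, an adhesion G protein-coupled receptor gene, was 10.6-fold higher, and Pcp4, which encodes a small calmodulin-binding protein, was 8.41-fold higher. Fmo1, a flavin-containing monooxygenase gene, was 13.3-fold higher, and Gsta2, a glutathione S-transferase gene, was 21.3-fold higher by its brighter probe. Both belong to families of close paralogs, so which member gave the signal is uncertain. Igf1, the growth factor gene, was 24.9-fold higher by the probe used (4.64 ± 0.37, adjusted p = 0.0405). Its other probes gave log2 fold changes between -0.19 and -0.11, so the rise rests on 1 probe. With normexp the log2 fold changes were 2.24 for Gsta2, 1.97 for Fmo1, 2.31 for Krt13, 2.28 for Adgrf5, 2.37 for Igf1 and 1.90 for Npy, and all 6 passed. Further genes were not well above background in the empty vector group and have only a lower bound, which holds for the processed signals used here. Arhgap24, a GTPase-activating protein gene, was at least 26.9-fold higher by this rule. For Arhgap24 the bound is the fitted fold itself, because its own signals exceeded the lowest signals well above background. Omp was at least 14.7-fold higher, and Kcnj16, a potassium channel gene, at least 7.02-fold higher. Rnase17 was at least 17-fold higher, with its paralogs leaving the source of the signal uncertain. With normexp the log2 fold changes lay below these bounds, at 1.95 for Arhgap24, 1.44 for Omp, 0.91 for Kcnj16 and 1.60 for Rnase17, and all 4 passed. From Spp1 to Rnase17, no gene named in this paragraph kept its call with the slide as a block.

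Among genes with a symbol that passed and were well above background on every array, the 12 that fell most lay between -2.40 and -1.30 on the log2 scale. After Nefm, Vcam1, a cell adhesion molecule gene, fell by 2.13 ± 0.16 (adjusted p = 0.0371). Adh7, an alcohol dehydrogenase gene, fell by 1.92 ± 0.14, Anxa3, an annexin gene, fell by 1.80 ± 0.14, and Dhrs3, a retinal reductase gene, fell by 1.75 ± 0.09. Cspg4, which encodes a cell surface proteoglycan, fell by 1.67 ± 0.14. Sulf2, a heparan sulfate sulfatase gene, fell by 1.51 ± 0.11, and Slit3, which encodes a secreted guidance protein, fell by 1.40 ± 0.10. The chemokine receptor gene Ackr3 fell by 1.34 ± 0.08, the sulfatase gene Arsi fell by 1.58 ± 0.13, Arxes1 fell by 1.48 ± 0.09 and Pln, which encodes phospholamban, fell by 1.30 ± 0.12. With normexp Vcam1, Sulf2 and Pln had -1.34, -0.87 and -0.70, and passed. All 12 were lower on both MAX vector arrays than on both empty vector arrays. None of the 12 passed with the slide as a block, where Nefm had an adjusted p of 0.0694.

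Of the 15 measured genes of catecholamine synthesis, storage and clearance, Th rose, Ddc fell and 13 did not pass over all genes. Adjusted over the list alone, 2 were higher (Th and Maob) and 1 lower (Ddc). Dbh, which encodes the enzyme that converts dopamine to noradrenaline, had a log2 fold change of -1.41 ± 0.89 (adjusted p = 0.511) and was well above background on 1 of the 2 MAX vector arrays. Slc18a1, a vesicular monoamine transporter gene, was likewise well above background on 1 of the 2 and had -0.84 ± 0.37 (adjusted p = 0.382). With normexp these 2 genes had -0.21 and -0.15. Maob, which encodes a monoamine-degrading enzyme, had 0.47 ± 0.09 (adjusted p = 0.139). Of the 35 measured genes of secretory granules and exocytosis, Npy rose and Snap25, a membrane fusion protein gene, was at least 2.37-fold higher (adjusted p = 0.0244), while 33 did not pass. With normexp Snap25 had a log2 fold change of 0.43 (adjusted p = 0.109), and its call was lost in 8 of 16 alternatives. The count adjusted over the list alone was also 2 higher and 0 lower. The granule protein genes Chga and Chgb had -0.07 ± 0.42 and 0.17 ± 0.29 (adjusted p = 0.947 and 0.803). Both were dim, with mean log2 signals of -3.76 and -4.13 with the empty vector and -3.84 and -3.96 with MAX. The arrays' medians over all probes lay between -3.393 and -3.235. Dbh and Slc18a1 were dimmer still, at -5.3 and -5.35 with the empty vector. Small changes of these genes thus say little about a chromaffin programme. Neither list passed as a whole (camera adjusted p = 0.936 and 0.155). Among 13 sympathoadrenal transcription factor genes 0 passed over all genes in limma, and 2 had an unadjusted p under 0.05. Phox2a, the 1 that was lower when adjusted over the list alone, had -0.74 ± 0.10 (adjusted p = 0.0864). Gata3 had -0.20 ± 0.10.

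**Figure D2:**
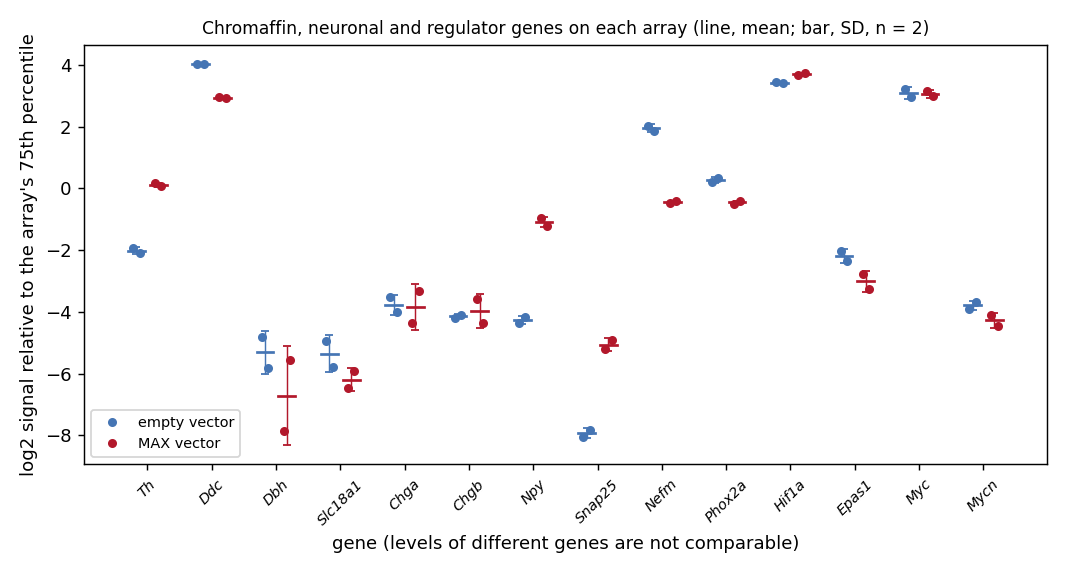
Log2 signal relative to the array's 75th percentile for 14 chromaffin, neuronal and regulator genes, with a point per array, the mean as a line and the SD as a bar (n = 2 per group). Th, Npy and Snap25 are higher and Ddc and Nefm lower on both MAX vector arrays, while the Dbh points of the groups overlap.

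The neuronal differentiation list was shifted down (camera adjusted p = 2.81e-05; adjusted p = 0.941 with an estimated correlation), with 21 of its 24 measured genes negative and a median log2 fold change of -0.48. Over all genes, Nefm fell and Mmp3 and Mmp10, genes of secreted proteases that nerve growth factor is known to induce, rose. Mmp10 was 7.9-fold higher (2.98 ± 0.14, adjusted p = 0.0197). Adjusted over the list alone, 14 were lower and 2 higher. Nefl, the light neurofilament subunit, had -2.06 ± 0.24 (adjusted p = 0.0691 over all genes), and Dcx, which encodes the microtubule protein doublecortin, -1.85 ± 0.30 (0.116), with 1 of the 2 MAX vector arrays well above background. Elavl4, which encodes a neuronal RNA-binding protein, had -1.31 ± 0.14 (0.0579) and Prph, which encodes peripherin, -0.92 ± 0.09 (0.0521). With normexp Mmp10, Nefl, Dcx and Elavl4 had 1.32, -0.84, -0.53 and -0.79 and passed (adjusted p = 4.42e-05, 0.00122, 0.049 and 0.00192 in limma). Prph, Thy1, L1cam and Ngfr also passed there, lower. Tubb3, Stmn2, Dpysl3, Elavl3, Ret and Plaur, lower over the list alone, did not. On slide 1 alone the median was -0.49 and the list kept its call (adjusted p = 5.46e-06).

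The mitotic genes were also shifted down: all 15 measured members of the G2 and M phase list were negative, with a median of -0.39 (camera adjusted p = 2.61e-05; adjusted p = 0.941 with an estimated correlation). In limma 0 passed by themselves, over all genes or over the list alone, and 10 had an unadjusted p under 0.05, all lower. With normexp Plk1 (-0.69, adjusted p = 0.00746 in limma) and Cdc25b (-0.57, adjusted p = 0.0234) passed over all genes, and the other members did not. Plk1, a mitotic kinase gene, had -0.55 ± 0.11, Ccna2, a cyclin gene, -0.49 ± 0.12 and Cdk1 -0.40 ± 0.11. On slide 1 alone 14 of the 15 were negative with a median of -0.50 (adjusted p = 1.19e-06). The 19 measured genes of the G1 and S phase and of DNA replication had a median of -0.19 (adjusted p = 0.155) and held 0 calls over all genes, with 4 at an unadjusted p under 0.05. Ccnd2, a D-type cyclin gene and the 1 that was higher when adjusted over the list alone, had 1.11 ± 0.15 (adjusted p = 0.0847), Ccnd1 0.02 ± 0.08 and Cdk4 0.00 ± 0.10. The cyclin-dependent kinase inhibitor genes Cdkn1a and Cdkn1b had -0.32 ± 0.11 and 0.28 ± 0.09 (adjusted p = 0.292 and 0.26). Of 6 measured genes of that list 0 passed over all genes (3 at an unadjusted p under 0.05) and 1, Cdkn1c, was higher over the list alone. The list's median was -0.13 where its mean was 0.04 (camera adjusted p = 0.978).

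Of the HIF genes, Hif1a had a log2 fold change of 0.27 ± 0.09 (adjusted p = 0.277), Epas1, which encodes HIF2α, had -0.81 ± 0.22 (adjusted p = 0.233) and their partner gene Arnt -0.04 ± 0.12. The 14 measured genes of the HIF machinery held 0 calls over all genes (4 at an unadjusted p under 0.05), and 1 higher, Bmal1, and 1 lower, Egln3, over the list alone. The median was 0.07 and the mean -0.06 (camera adjusted p = 0.817). Egln3, a HIF prolyl hydroxylase gene, had -0.84 ± 0.13 (adjusted p = 0.109). Of 29 measured hypoxia-induced genes, 0 passed over all genes (15 at an unadjusted p under 0.05), while 6 were higher and 4 lower when adjusted over the list alone. The median was 0.13 and the mean 0 (camera adjusted p = 0.291). The members lay on both sides of 0, with Aldoc, a glycolytic aldolase gene, at 0.89 ± 0.12 and Ddit4 at 0.81 ± 0.11. Angptl4 was at -1.80 ± 0.22. With normexp Epas1 had -0.44 and Angptl4 -0.69. Hypoxia-induced genes that passed with normexp included Bnip3l, Aldoc and Ddit4, higher (adjusted p = 0.00383, 0.00886 and 0.0126 in limma). Lower ones included Egln3, Adm and Angptl4 (0.000723, 0.0042 and 0.0116). Vegfa had 0.45 ± 0.09 (adjusted p = 0.151). The 22 measured glycolysis genes were shifted up with a median of 0.15 (camera adjusted p = 0.0484; adjusted p = 0.941 with an estimated correlation). The call was lost with the slide as a block (adjusted p = 0.385, median 0.10) and without empty vector replicate 1 (0.0948, median 0.09) or 2 (0.0813), and it held under 9 of 19 alternatives. The list held 0 calls over all genes (8 at an unadjusted p under 0.05) and 1 higher, Aldoc, over the list alone.

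The MAX and MYC network list, with 8 measured genes, had a median of -0.02 and 0 calls over all genes or over the list alone (2 at an unadjusted p under 0.05; camera adjusted p = 0.741). The 8 include Pias2 (0.10 ± 0.12), which was matched to the listed alias Miz1 and does not stand in the list by its own symbol. The list's median and test thus include a gene that may not belong to the network. Myc had -0.01 ± 0.15, Mycn -0.48 ± 0.16 (adjusted p = 0.299) and Mxi1, which encodes another MAX partner, 0.17 ± 0.11. Odc1, which encodes the first enzyme of polyamine synthesis and is a known MYC target, had -0.56 ± 0.10 (adjusted p = 0.137) and Ncl, which encodes nucleolin, -0.13 ± 0.11. The 29 measured ribosome biogenesis genes had a median of 0.02 (adjusted p = 0.291), and the 25 genes of nucleotide, polyamine and one-carbon synthesis a median of -0.13 (adjusted p = 0.185). Each list held 0 calls over all genes and 0 over the list alone, with 1 and 4 at an unadjusted p under 0.05. With the slide as a block, the list of nucleotide, polyamine and one-carbon synthesis passed, lower (adjusted p = 0.014), as did the G1 and S phase list (adjusted p = 0.0127), and without MAX vector replicate 2 ribosome biogenesis passed, higher (adjusted p = 0.0351). The 46 cytosolic ribosomal protein genes were shifted up by a median of 0.08 (camera adjusted p = 0.0117; adjusted p = 0.941 with an estimated correlation), and the 24 autophagy and lysosome genes by 0.17 (adjusted p = 0.00728; adjusted p = 0.941 with an estimated correlation). On slide 1 alone these medians were 0.02 and 0.08, and with the slide as a block the adjusted p values were 0.702 and 0.172. Both were also lost without empty vector replicate 1 (adjusted p = 0.0948 for each, medians 0.07 and 0.09), and the medians were 0.12 and 0.26 without empty vector replicate 2 and 0.15 and 0.24 without MAX vector replicate 2. Both lists held 0 calls over all genes and over the list alone, with 1 and 5 at an unadjusted p under 0.05. Ctsl, which encodes the protease cathepsin L, had 0.47 ± 0.10.

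**Figure D3:**
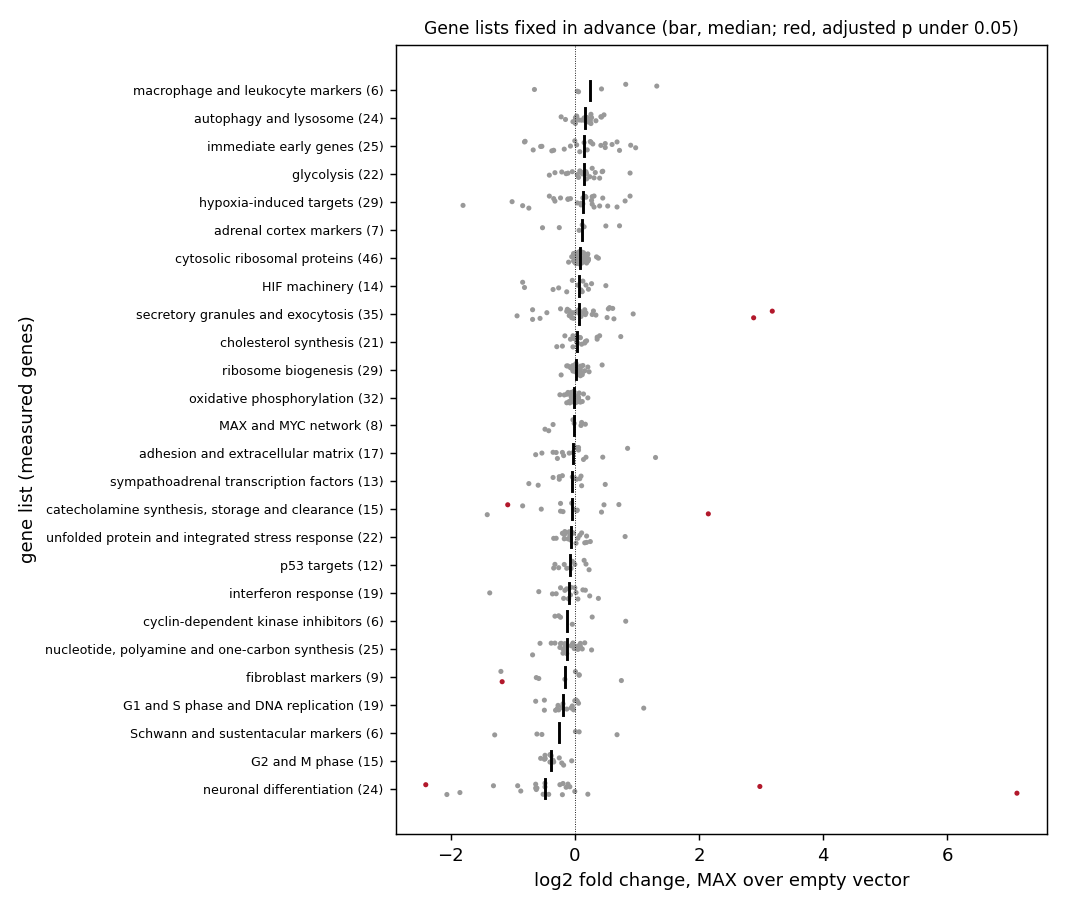
Log2 fold change of MAX vector over empty vector cells for each measured gene of the 26 gene lists tested, with the number measured in parentheses, the list median as a bar and genes with an adjusted p under 0.05 in limma in red. The neuronal differentiation list has a median of -0.48 and the G2 and M phase list -0.39; both went down under each scaling tried.

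The other lists did not pass camera's test, and all but fibroblast markers held 0 calls over all genes. Their medians were -0.01 for oxidative phosphorylation (adjusted p = 0.993), -0.07 for p53 targets (0.568), 0.04 for cholesterol synthesis (0.216; 0.0282, higher, without MAX vector replicate 2) and -0.10 for the interferon response (0.414). The unfolded protein and integrated stress response had a median of -0.06 and a mean of 0 (0.963), and adhesion and extracellular matrix a median of -0.03 and a mean of 0.03 (0.817). Immediate early genes had a median of 0.15 (0.817), up in camera and down in fry, and of -0.03 and 0.30 without empty vector replicate 1 and 2. Adjusted over the list alone, immediate early genes held 2 higher (Nr4a1 and Dusp6) and 6 lower, Fos and Fosl1 among them. Adhesion and extracellular matrix held 3 higher (Cdh1, Itga1 and Fn1) and 2 lower (Cdh2 and Col5a1). Cholesterol synthesis held 1 higher, Tm7sf2, and the unfolded protein response 1, Ddit4. In oxidative phosphorylation, p53 targets and the interferon response 0 passed over the list alone, with 0, 2 and 2 at an unadjusted p under 0.05. Among markers of other cell types, Tagln, which encodes the actin-binding protein transgelin and stood in the fibroblast list, fell by 1.17 ± 0.10 (adjusted p = 0.0477). Over the list alone, 1 of the 9 fibroblast markers was higher (Dcn) and 4 lower (Tagln, Lum, Pdgfrb and Thy1). Their median was -0.16, with an adjusted p of 0.205 in camera (0.00465, lower, with normexp) and 0.0247 in fry, which tests whether the genes move one way on balance. Macrophage and leukocyte markers had a median of 0.24 (adjusted p = 0.205; 0.0436, higher, with every probe tested by itself), with 2 of 6 higher over the list alone, Cd14 and Lyz2, the lysozyme gene at 1.32 ± 0.15. Adrenal cortex markers had a median of 0.12 (0.776) and Schwann and sustentacular markers -0.26 (0.466), each with 0 over the list alone and 1 at an unadjusted p under 0.05. These 3 medians were 0.75, 0.26 and -0.01 without MAX vector replicate 1, and 0.03, -0.12 and -0.33 without MAX vector replicate 2. Of the endothelial markers 1 was measured, Kdr, with a log2 fold change of 1.98 ± 0.23 (adjusted p = 0.0701), and the list was not tested. With normexp Kdr had 0.62 and Lyz2 0.34.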

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

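All alternatives were planned before the data were examined, except the test of symbol-bearing genes alone, which was chosen after seeing the data. The sign of the called genes says little about stability, since they were chosen for differences large against their error. The calls numbered 794 with normexp (54% higher, against 68.5%), 541 with median scaling (474 at least 2-fold), 515 with the filter on all 4 arrays (60.6% higher), and 56 with the filter on 1 array (56 at least 2-fold, 83.9% higher). They numbered 955 with an intensity trend (386 at least 2-fold, 56.9% higher) and 655 at an adjusted p under 0.10 (388 at least 2-fold, 58% higher). Of the 794 and 955, 172 and 199 were among the 213. With no filter 0 genes passed in limma, 0 at least 2-fold (4033 at an unadjusted p under 0.05; smallest adjusted p = 0.0501). With genes with a symbol alone, 279 passed (61.3% higher). Quantile scaling gave 293, the mean of probes 205, robust moderation 211 and 213 passed with the authors' values. The cause of these differences was not tested. No paired analysis was used as the main result, since no label ties a replicate number to a passage. The correlation of deviations of samples with the same replicate number was -0.018, so no shared effect was seen. This does not exclude a shared passage effect, as MAX vector replicate 1 alone lay on slide 2. With the replicate block, 0 genes passed, 0 at least 2-fold (3885 at an unadjusted p under 0.05). The slide as a block left 8 genes, 8 at least 2-fold and 100% higher, with fewer arrays behind the test. Leaving out an array gave 0 to 144 calls, 0 to 144 at least 2-fold, and 49.3% to 100% higher where any passed; 0 passed without empty vector replicate 1 or 2 (1963 and 2456 at an unadjusted p under 0.05), 8 without MAX vector replicate 1, and 144, of which 71 among the 213, without MAX vector replicate 2. There the lone array is assumed to vary like the other group, and fewer samples enter the test.

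Of the 213, 26 had several probes; tested by itself, every probe kept the sign in 23 of them and not in 3, Igf1 among them (-0.11 and -0.19 by its other probes). With normexp, further log2 fold changes over 1.5 times smaller were 0.54 for Ccnd2, 0.21 for Maob and -0.16 for Mycn. Genes near 0 changed sign. With normexp Ccnd1 was -0.02, Cdk4 0.07, Myc 0 and Chga 0.02. Cdk4 was 0.02 and Myc 0 with quantile scaling, and 0.02 and 0.01 with median scaling. With the mean of probes Ccnd1 was -0.06, and with the slide as a block Chgb was -0.21, Arnt 0.08 and Chga 0.45. With an array left out, the ranges were -0.21 to 0.55 for Chgb, -0.08 to 0.08 for Cdk4, -0.15 to 0.12 for Myc, -0.15 to 0.08 for Arnt and -0.60 to 0.45 for Chga. Among uncalled genes of the naming rule, Ccnd2 and Phox2a passed with normexp, with the filter on all 4 arrays and with an intensity trend. Odc1 passed with normexp and the trend. Of genes named beyond the rule, others passed with normexp, among them Egln3, Prph, Nefl, Elavl4, Cdh1, Epcam, Plk1, Aldoc and Kdr.

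The G2 and M phase and neuronal differentiation lists passed under 17 of 19 alternatives each, all but the estimated correlation (adjusted p = 0.941) and fry (0.21); autophagy and lysosome passed under 13, cytosolic ribosomal proteins under 11 and glycolysis under 9. Lists that turned direction had not passed. Their adjusted p values were 0.961 for oxidative phosphorylation and 0.8 for catecholamine genes with normexp. With median scaling they were 0.942 for oxidative phosphorylation and 0.966 for the unfolded protein response. With no filter they were 0.609 for cyclin-dependent kinase inhibitors, 0.828 for HIF machinery, 0.81 for immediate early genes and 0.828 for Schwann markers. They were 0.894 for catecholamine genes with the filter on all 4 arrays and 0.992 for oxidative phosphorylation with that on 1. With the mean of probes they were 0.992 for kinase inhibitors and 0.988 for adhesion, and with the replicate block 0.978 for kinase inhibitors and 0.978 for catecholamine genes. With the slide as a block they were 0.951 for ribosome biogenesis, kinase inhibitors and HIF machinery, and with fry 0.641 for catecholamine genes and 0.674 for immediate early genes. With an array left out, the ranges were 0.363 to 0.987 for the MAX and MYC network, 0.0351 to 0.951 for ribosome biogenesis, 0.162 to 0.965 for oxidative phosphorylation, 0.894 to 0.987 for kinase inhibitors and 0.607 to 0.987 for catecholamine genes. They were 0.697 to 0.965 for HIF machinery, 0.616 to 0.894 for the unfolded protein response, 0.0869 to 0.987 for the interferon response, 0.18 to 0.951 for immediate early genes and 0.201 to 0.863 for adrenal cortex markers. Of lists without a call, 6 passed under some of the 19 alternatives. In all tallies over the 19, the slide as a block and MAX vector replicate 1 left out are the same fit, so it counts more than once. The authors' values and the adjusted p under 0.10 all but repeat the main test of the lists, so their outcome was given in advance. All alternatives but the estimated correlation and fry kept the preset correlation of 0.01, so the tallies say little about that setting. The G1 and S phase list passed, lower, under 5: normexp (0.0186), every probe by itself (0.0436), an intensity trend (0.049), and the slide as a block and MAX vector replicate 1 left out (0.0127 each). Nucleotide synthesis passed, lower, under 3: every probe by itself (0.0296) and the last 2 (0.014 each). Fibroblast markers passed, lower, under 2: normexp (0.00465) and fry (0.0247). Under 1 each passed, higher, macrophage markers (every probe by itself, 0.0436), cholesterol synthesis (0.0282) and ribosome biogenesis (0.0351), the last 2 without MAX vector replicate 2. Signal over background limits the dim genes: 32 of the 146 higher calls were well above background on neither empty vector array.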

Other observations

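The tests of chance placement, of shared signal within families, of divergence between the lines and of the ribosome biogenesis genes were chosen only after the result was seen. Several genes that rose were neighbours among the 6285 tested genes with a symbol, put in the order of assembly GRCr8. Genes not tested or not named can lie between them, and words such as beside refer to this order. Next to each other lay Krt13, Krt15 and Krt19, and Mmp12, Mmp3 and Mmp10, of which Mmp12, a macrophage metalloelastase gene, was at least 12.8-fold higher (adjusted p = 0.0405 in limma). Hsd11b1, which encodes a glucocorticoid-activating enzyme, was 4.28-fold higher beside G0s2, which encodes an inhibitor of triglyceride breakdown and was 7.81-fold higher. Prrx1, a homeobox transcription factor gene, was 5.72-fold higher beside Fmo1 and Fmo2; the latter was 7.07-fold higher. Map2k6, a stress kinase gene, was 3.4-fold higher beside Kcnj16, and Igsf5 was 2.5-fold higher beside Pcp4. With normexp the log2 fold changes were 1.39 for Mmp12, below its bound, 1.39 for Hsd11b1, 2.39 for G0s2, 1.32 for Prrx1, 1.57 for Fmo2, 1.15 for Map2k6 and 0.61 for Igsf5, and all passed. These genes were named here after their values were seen.

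Of 91 called genes with a symbol, 21 lay in 9 groups of neighbours at most 3 tested genes apart and changed the same way, all higher, where permuted calls gave a mean of 2.24 groups (permutation p = 1e-04, one-sided, the smallest that 10000 permutations can give). As pairs, 15 were seen against a permuted mean of 2.31 (permutation p = 1e-04, again the smallest). Pairs of different families, which shared signal between paralogs would not join by itself, numbered 7 against a mean of 2.22 (permutation p = 0.006). Prrx1 counts there with both Fmo1 and Fmo2, which are paralogs, so that count is not free of their effect. For the 8 pairs within a family, shared signal stays open because probe sequences were not compared. Neighbours also varied together somewhat without MAX. Differences between the 2 empty vector arrays had a Spearman correlation of 0.026 over all neighbour pairs, against 0.071 for the log2 fold changes. For permuted fold changes the upper limit was 0.014. Permuted calls are therefore a lenient comparison. A copy number change reaching 5 tested genes to each side is argued against, since the 91 flanking genes had a median of 0 on the log2 scale after turning to the pair's direction, with 45 in the same direction and 46 in the other; a narrower change stays open. A candidate explanation is that some stretches of the genome became active together in the MAX vector line, which cannot be told apart from divergence of the lines for reasons other than MAX, as each group is 1 line; 50.2% of all genes had groups that did not overlap, against 33.3% by chance.

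Of 146 symbol families tested with camera, 4 passed: keratins, olfactory receptors, Zbtb (adjusted p = 0.0341, median 0.17) and Hsd (adjusted p = 0.0473, median 0.28), each with an adjusted p = 0.996 with an estimated correlation. In the keratin family, with 3 called members, 9 of 11 measured keratin genes were positive, with a median log2 fold change of 0.76 (adjusted p = 2.92e-05), and the median stayed between 0.73 and 0.82 under each scaling and on slide 1 alone. As to epithelial cells in the MAX vector cultures as a possible explanation, of 15 measured epithelial markers besides Krt13, Krt15 and Krt19, 4 of them keratins too, 14 were positive with a median of 0.36 and 0 passed in limma (10 at an unadjusted p under 0.05), with Epcam at 0.97 ± 0.11 (adjusted p = 0.0674) and Cdh1, the E-cadherin gene, at 1.30 ± 0.21 (adjusted p = 0.117). With the empty vector, 12 of the 15 already lay above the median level of all genes, where a small share of other cells would not show, among them Spint2 (log2 signal 3.13 with the empty vector, 3.19 with MAX), Jup (3 and 3.56), Itgb4 (2.70 and 3.57) and Spint1 (1.94 and 1.99), and the other 3 had a median change of 0.44. With normexp, Itgb4, Cdh1, Epcam, Krt18 and Krt5 passed, with log2 fold changes of 1.01, 0.92, 0.87, 0.73 and 0.73. The others of the 15 did not. The marker list does not hold every epithelial gene. Outside it, Tp63 and Lgals7 passed in the main fit, higher (log2 fold changes 1.15 and 2.04, and 1.12 and 1.03 with normexp). These 2 were picked after their values were seen, and epithelial genes outside the list that did not rise were not counted. With so few low-level markers, other cells and a change within PC12 cells cannot be told apart.

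Ribosome biogenesis genes, a class that MYC proteins are known to raise, were tested as a hypothesis of a MYC response in the line given MAX. Of the 29 measured, 26 had an upper 95% limit under 0.5 on the log2 scale, and the highest limit was 0.68, so error could hide a rise of 0.5 in few of them. The direction of the list depended on the arrays: its adjusted p was 0.0351, upward, without MAX vector replicate 2 and 0.951, downward, without MAX vector replicate 1.

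Olfactory receptor genes form a large family with paralogs, so single members are uncertain. Their median was -0.35 over 205 genes (adjusted p = 0.00798 in camera, 0.996 with an estimated correlation). It was -0.07 with normexp and 0.04 on slide 1 alone, which leaves out MAX vector replicate 1. Without MAX vector replicate 2 it was -0.67.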
